A study of Rattus norvegicus with 23 samples.

How the data were processed

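Periodontal ligament is the fibrous tissue that holds a tooth root in the alveolar bone. Per the labels' protocols, it was scraped from the roots of extracted first mandibular molars of male Wistar rats that were 4 weeks old at the start, total RNA was extracted with a column kit, and labelled cDNA made from 200 ng of RNA was hybridised to Affymetrix whole-transcript arrays. The 23 arrays came from 12 animals, 6 control and 6 experimental, killed at 31 or 43 days of age, with 3 animals of each condition at each age. Of these, 11 animals gave a right and a left molar, and 1 experimental animal of 31 days, E2, gave a right molar only. The series title speaks of unopposed molars, meaning teeth whose opposing tooth is missing. The labels mark both molars of an experimental animal as experimental and do not say which side lost its antagonist, so neither side was taken as untreated. The numeral in the sample titles was taken as the animal, and animals are named here C1 to C6 for control and E1, E2, E3, E4, E5 and E7 for experimental.

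The deposited table gives log2 values that the authors made with RMA and Partek, per the submitters' processing notes. No version, order of steps or settings of those tools were given in the sources used here. RMA corrects background, normalizes between arrays and sums the probes of a probe set on the log2 scale. The values were used as deposited in the primary analysis, with no further scaling. They cover 36685 probe sets, and no column of another sample was present. The platform table lists 19086 of these probe sets. Of them, 18511 have 1 gene symbol and 575 have several, while 17599 probe sets have no listed symbol. Entrez identifiers of 18394 probe sets matched the RefSeq table of assembly GRCr8, which changed 0 symbols and was used for names only, so no coordinates are given. Probe sets with 1 symbol represent 18166 genes. A gene with several probe sets was represented by the probe set with the highest mean over all arrays. Genes whose mean was below the 25th percentile (5.81 on the log2 scale) were left out, which left 13624 genes. Arrays carry no read depth, and their number limits the precision.

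Differences were tested in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Means of the 8 groups formed by condition, side and age were fitted to all 23 arrays, so that all groups shared 1 estimate of the spread. The animal was a random block, with an estimated correlation of 0.504 between molars of an animal. It was 0.182 with the set of arrays, described below, as a block and 0.258 after quantile normalization, so 0.504 holds part of the shift between sets, as each animal lay in 1 set. The contrasts were tested with moderated statistics, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with 0.05 as the threshold. Standard errors (SE) after a log2 difference come from this fit. The 15 comparisons, their tests, 32 gene lists and most of the alternatives listed further on were fixed before the data were examined. So was the rule for naming genes: per comparison and direction, up to 10 genes past the threshold with the largest differences (up to 5 for comparisons of a single side, between sides or between conditions' age effects), the genes with the smallest unadjusted p to make up 5, and up to 4 members of each list with the smallest p. Genes that missed the threshold are given as values only. Symbols of placeholder loci and of olfactory receptors were passed over for naming.

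The lists cover 16 pathways or lineages of connective tissue and bone and 16 other cell types that a scraped sample can hold. Of the salivary gland list, 0 of 8 members were among the genes tested, so it has no result. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. Camera with an estimated correlation and fry, a rotation test of the list by itself, were run beside it. Camera for the right-left comparisons within a condition, for single sides and their difference at 43 days, and for the difference between the age effects was added after the data were examined, as were values of single lists with each animal left out. A count of list members "adjusted over the list alone" uses only the p-values of that list. Differences between the molars of an animal were also tested with exact sign-flip tests, all of them two-sided, which cannot give a p below 0.0625 with 5 pairs or below 0.03125 with 6.

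The medians of the arrays fell into 2 sets, described with the results. The labels name no such sets, so this was seen only after the data were examined. Every comparison was then repeated with the set as a block, and within each set where it held both sides of the contrast. Each set held experimental animals of 1 age. Within-set values of comparisons over both ages that include experimental animals are therefore those of that age. Correlations of deviations from group means were computed to see whether arrays pair. Over the 11 pairs of molars from 1 animal their median was 0.235 (-0.418 to 0.765), with 8 above 0.1. The animal is a block because both molars come from it. Numerals were not used to pair animals across conditions. No 2 arrays held the same values throughout. The labels do not say whether arrays were run on separate days. The p-values of single genes and of sign-flip tests therefore measure the spread between these animals together with any technical spread. Camera p-values with the preset correlation of 0.01 rest on near independence between genes and do not measure that spread. Among oral epithelium genes the mean correlation was 0.884 after group means were removed, so such p-values can be far too small.

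The fit was tested on simulated data with 13624 genes, animal correlation and array numbers as here, and known changes in 100 genes per size. For experimental against control animals at 31 days it recovered 69 of 100 genes changed by 1 log2 unit and 98 of 100 changed by 2, with 9 unchanged genes called. For both ages together it recovered 95 and 100, with 8 unchanged genes called. For right against left molars of experimental animals it recovered 94 and 98, with 10 unchanged genes called. The simulation held neither sets of arrays nor differences in tissue makeup.

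Alternatives fixed in advance were no filter and a filter at the 50th percentile, no replicate block, the animal as a fixed block, 1 value per animal, the numeral as a block across conditions, quantile normalization and median centring, trend and robust variance estimates, array weights, the probe set with the largest variance per gene, fits to only the groups compared, a minimum of 1.5 fold, and leaving out each animal. Added after the data were examined were the set of arrays as a block, fits within sets, the mean of the oral epithelium list as a covariate, leaving out the 2 arrays with the lowest correlation (C2 left and E3 left, 0.891), and another algorithm for array weights. Probe sets without a listed symbol were left out of the comparisons of genes and tested apart. Those with several symbols were not tested.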

Results

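The series measured gene expression in the periodontal ligament of rat first mandibular molars, in animals with unopposed molars and in controls, at 31 and 43 days of age. Condition, side and age formed 8 groups of 3 arrays, except that the left molars of experimental animals at 31 days gave 2 arrays. All differences are on the log2 scale, as the first group named minus the second, and each was estimated for 13624 genes.

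The 23 arrays fell into 2 sets by their medians. The 11 arrays of animals E1, E2, E3, C1, C3 and C4 had medians of 6.50 to 6.77, and the 12 arrays of E4, E5, E7, C2, C5 and C6 had medians of 6.01 to 6.18. With limma, 8099 genes differed between the higher and the lower set, 8090 of them higher in the higher set, and quantile normalization reduced this to 156 genes. The sets were parted at the largest gap between these medians, so the count and direction as deposited follow largely from that choice. All experimental animals of 31 days lay in the higher set and all those of 43 days in the lower set, while controls of both ages lay in both. Oral epithelium markers also varied widely: the mean of the 16 measured keratin, desmosome and related genes, after quantile normalization, ran from 7.88 in the right molar of E4 and 7.91 in the left molar of C2 to 11.89 in the left molar of C5 and the right molar of E7. These genes moved as a block, with a mean pairwise correlation of 0.884 after group means were removed. Skeletal muscle markers were highest in the right molars of E7 (8.02) and E1 (7.95) and the left molar of E1 (7.36), and were at most 6.96 in the other arrays. Erythroid markers ran from 8.07 in the right molar of E1 to 10.70 in the left molar of C2.

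**Figure D1:**
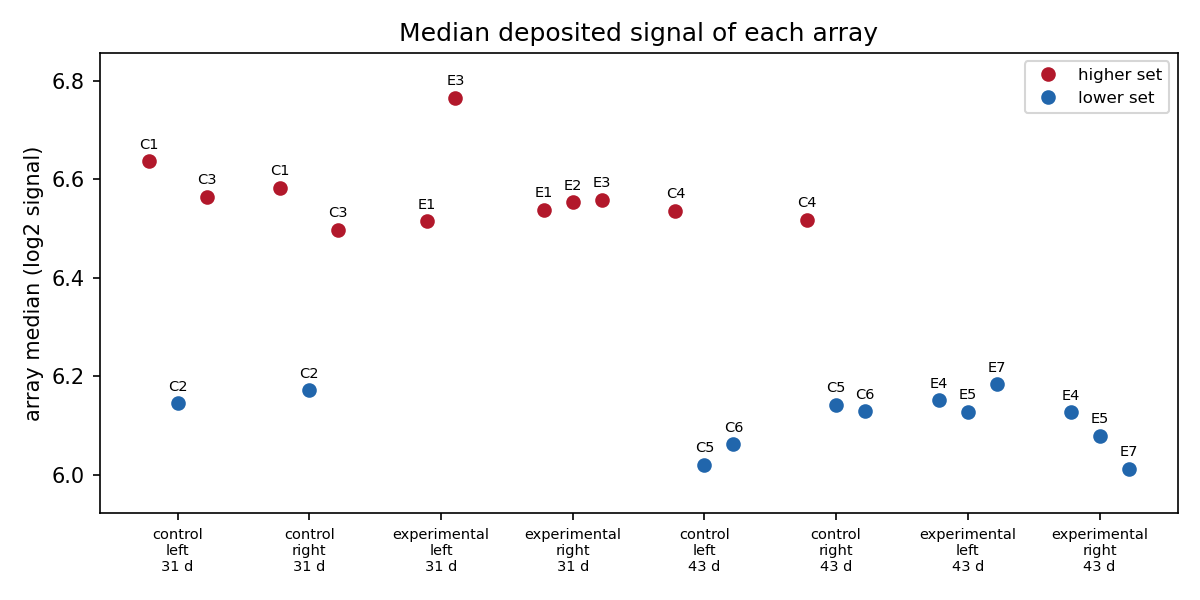
Median log2 value of each array (vertical axis) by condition, side and age, with 1 point per array coloured by set. The higher set spans 6.50 to 6.77 and the lower set 6.01 to 6.18, and the 2 sets part the ages of the experimental animals but not those of the controls.

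**Figure D2:**
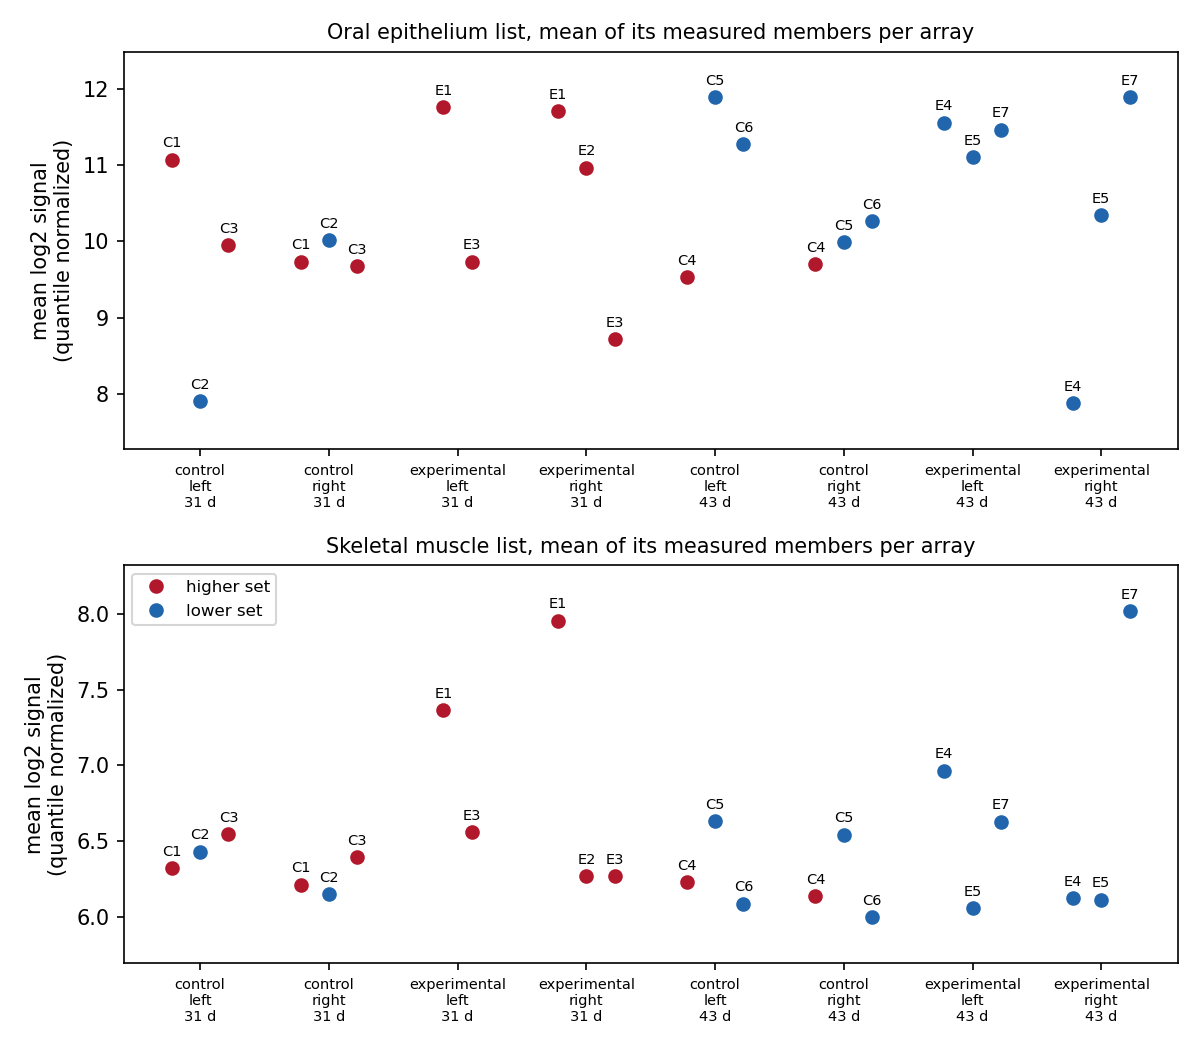
Mean quantile-normalized log2 value of the oral epithelium and skeletal muscle lists, with 1 point per array by group, coloured by set. Epithelium ranges from 7.88 to 11.89, and muscle exceeds 7 in both molars of E1 and in the right molar of E7.

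At 31 days, matrix, bone and vessel genes lay lower and epithelial and muscle genes higher in the ligament of experimental animals than of controls (3 animals each). All 29 measured genes of the fibrillar collagen list were lower, with a median of -0.32; examples are Col6a2 (-0.70 ± 0.26 SE) and Col6a3 (-0.82 ± 0.32). Of 19 ligament and tendon fibroblast genes 17 were lower (median -0.31), among them Fmod, a proteoglycan that binds collagen fibrils, at -1.92 ± 0.51. Matrix proteases had a median of -0.26, with 20 of 25 lower, and osteoclast genes one of -0.44, with 9 of 11 lower; Mmp9, a protease of osteoclasts, was at -1.31 ± 0.43 and Ctsk at -0.72 ± 0.40. Osteoblast genes were lower in 23 of 29 (median -0.14). Endothelial genes were lower in 11 of 12 (median -0.54), with the VEGF receptor Flt1 at -0.73 ± 0.27, and smooth muscle genes in 8 of 10 (median -0.39), with the contractile genes Myl9 at -1.14 ± 0.39 and Tagln at -1.39 ± 0.53. Macrophage (median -0.36), granulocyte (-0.50) and erythroid (-0.29) lists lay lower too. All 10 skeletal muscle genes were higher (median 0.66), with myoglobin, Mb, at 1.22 ± 0.73, and so were all 16 oral epithelium genes (median 0.83), with the keratin Krt76 at 2.36 ± 1.49.

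No gene passed at 31 days in limma (smallest adjusted p 0.954), and 320 had an unadjusted p under 0.05. That is a smaller share of the 13624 genes than the 0.05 expected without any difference. The same held, as deposited, for experimental against control animals at 43 days, over both ages and by side. With the set as a block 0 genes passed at 31 days and 1394 had such a p. By camera 18 lists passed, 16 lower and 2 higher: collagen with an adjusted p of 2.24e-12, endothelium 2.08e-12, ligament fibroblast 1.21e-07, proteases 1.19e-07, osteoclast 7.67e-07, osteoblast 0.000436, skeletal muscle 0.00446 and oral epithelium 0.0105. With an estimated correlation none passed: the adjusted p was 0.454 for collagen, ligament fibroblast and protease genes, 0.416 for endothelium and osteoclast, 0.589 for osteoblast, 0.522 for skeletal muscle and 0.662 for oral epithelium. Signalling lists that passed with smaller medians were TGF-beta and BMP (-0.16), IGF, FGF and PDGF (-0.16), YAP and stretch targets (-0.09), interferon (-0.05), the unfolded protein response (-0.05) and Wnt (-0.03), with adjusted p from 0.486 to 0.662 with an estimated correlation. Adjusted over the list alone, 1 ligament fibroblast gene passed, lower, and 0 collagen genes. Within the higher set, which held 3 experimental and 2 control animals of this age, the collagen median was -0.46 with 0 of 29 higher, Fmod was at -2.04 ± 0.32, and epithelium and muscle were at 0.39 and 0.52. The median of all genes was 0.09 as deposited and -0.05 with the set as a block, where the collagen median was -0.58. Much of this rested on E1, whose arrays had much epithelium and muscle. Its skeletal muscle means were 7.36 and 7.95, against 6.27 to 6.56 in E2 and E3 and 6.15 to 6.55 in the controls of this age. Without E1 8 of the 18 lists passed. The medians were then 0.30 for skeletal muscle (adjusted p 0.209), 0.26 for oral epithelium (0.527), -0.05 for ligament fibroblast (0.157), -0.06 for protease (0.145), 0.04 for osteoblast (0.878), -0.04 for granulocyte (0.542) and 0.16 for erythroid genes (0.492), and none of these passed. Collagen passed, at -0.11 (0.0178). Without the arrays C2 left and E3 left the granulocyte median was -0.19.

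**Figure D3:**
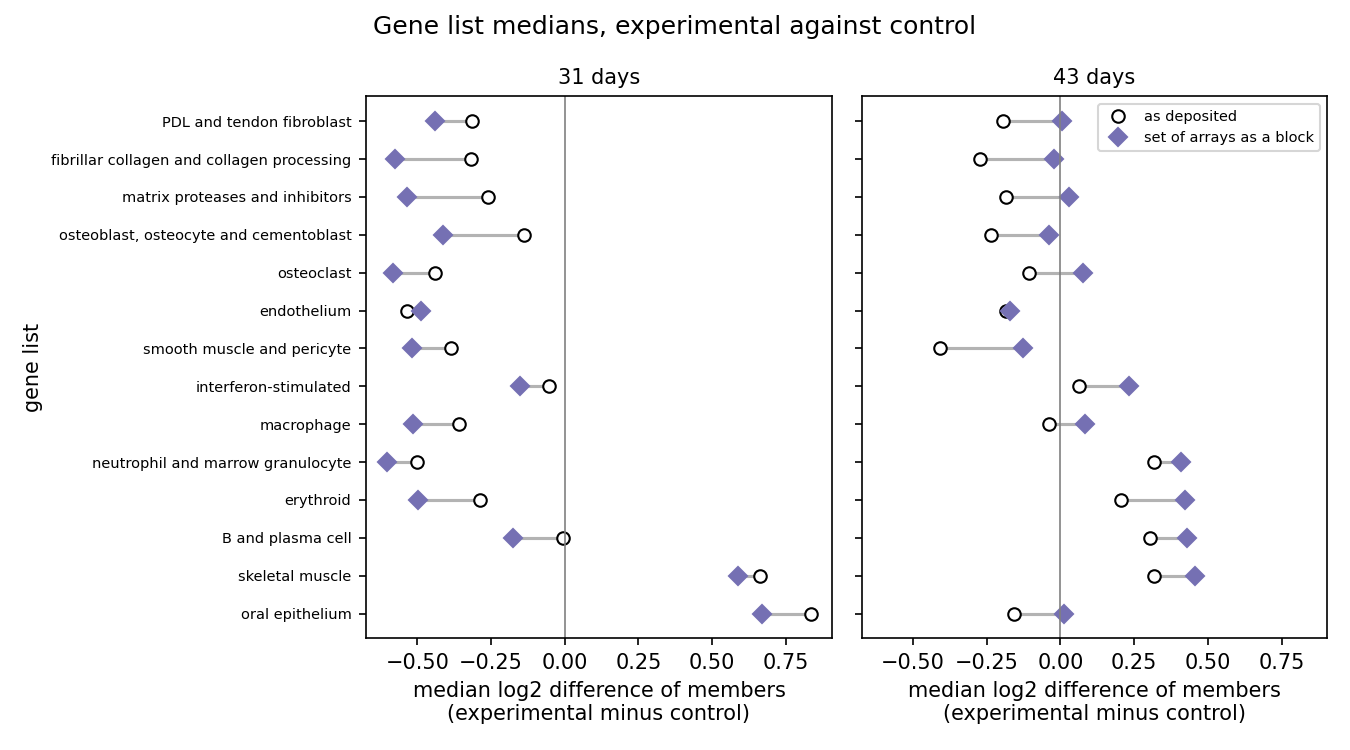
Median log2 difference, experimental minus control, of 14 gene lists at 31 and 43 days, as deposited (open circles) and with the set of arrays as a block (diamonds). Collagen lies at -0.32 and -0.58 at 31 days and at -0.27 and -0.02 at 43 days.

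At 43 days, genes of white and red blood cell lineages lay higher in experimental than in control animals (3 animals each), measured against a median of all genes of -0.13. Granulocyte genes were higher in 10 of 14 (median 0.32), with the neutrophil granule gene Ngp at 1.16 ± 0.78 and Fcnb at 0.91 ± 0.63. B and plasma cell genes were higher in 8 of 9 (median 0.30), with Jchain, the joining chain of immunoglobulins, at 1.28 ± 0.71 and the receptor gene Cd79a at 0.78 ± 0.51. All 8 erythroid genes (median 0.20) and 5 of 6 T and NK cell genes (median 0.15) were higher, as were 8 of 14 interferon-induced genes (median 0.06), including Irf7 (0.44 ± 0.29) and Mx1 (0.38 ± 0.23). By side, the granulocyte median was 0.63 in right and -0.01 in left molars, that of B cell genes 0.74 and 0.04, of erythroid genes 0.67 and -0.11 and of T and NK cell genes 0.46 and -0.11, against medians of all genes of -0.10 and -0.16. In left molars camera still called granulocyte (adjusted p 0.0276) and B cell genes (0.0174) higher, each 0.744 with an estimated correlation. Skeletal muscle genes had a median of 0.32 with E7 and of -0.07 without it, with 2 of 10 higher. Wnt genes had a median of -0.31, with Wnt5a at -0.70 ± 0.20, TGF-beta and BMP genes one of -0.27, with Ltbp1, a TGF-beta binding protein, at -0.60 ± 0.22, and IGF, FGF and PDGF genes one of -0.37. Single genes with the smallest p included Ly6c (1.24 ± 0.42), cysteine dioxygenase, Cdo1 (-0.99 ± 0.26), Dpyd, of pyrimidine breakdown (-0.78 ± 0.22), and the clock gene Per2 (-0.60 ± 0.18).

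No gene passed at 43 days in limma (smallest adjusted p 0.960), with 170 at an unadjusted p under 0.05, and 15 lists passed by camera, 11 higher and 4 lower. Adjusted p was 4.8e-09 for B and plasma cell, 5.98e-09 for granulocyte, 5.81e-06 for skeletal muscle, 1.27e-05 for interferon, 2.01e-05 for erythroid, 4.37e-05 for T and NK cell, 0.000418 for Wnt, 0.00197 for TGF-beta and 0.00539 for IGF genes. With an estimated correlation none passed: adjusted p was 0.401 for erythroid, 0.338 for the other blood lineages named, interferon and skeletal muscle, and 0.62 for the 3 signalling lists. Early response genes were also called higher (median 0.01, adjusted p 1.87e-05, and 0.338 with an estimated correlation), as were macrophage (-0.04), inflammatory (-0.12) and adipocyte (0.00) genes, whose medians lay at or below 0 but above that of all genes. Oral epithelium genes were called higher too, with a mean of 0.16 but a median of -0.16, which lies below that of all genes. Their median was 0.19 in left molars (14 of 16 higher) and -0.42 in right ones (4 of 16), and the list did not pass without E7 (adjusted p 0.935) or C4 (0.101). For these 4 lists the adjusted p was 0.62 with an estimated correlation. Without E7 the skeletal muscle list did not pass (adjusted p 0.314), nor did Wnt (0.0797 without E7, 0.104 without C4) or TGF-beta genes (0.215 and 0.0684). The difference between the sides in the blood lineages was itself called by camera. The right-left difference was higher in experimental animals by a median of 0.76 for granulocyte (adjusted p 0.00352), 0.87 for B cell (0.00493), 0.62 for erythroid (0.0411) and 0.59 for T and NK cell genes (0.00352), each 0.912 with an estimated correlation. Lists of other tissues moved too: cell cycle genes were higher (0.21, 0.0101), and oral epithelium (-0.51, 0.0101), endothelium (-0.24, 0.00493), chondrocyte (-0.21, 0.00836), ligament fibroblast (-0.11, 0.00614), collagen (-0.07, 0.0307) and protease genes (-0.08, 0.0411) lower. The adjusted p of each of these 7 was also 0.912 with an estimated correlation. Collagen genes had a median of -0.27 and did not pass (adjusted p 0.232). Within the lower set, with 3 experimental and 2 control animals of this age, the granulocyte and B cell medians were both 0.55, erythroid 0.36, Wnt -0.06, and collagen 0.07 with 22 of 29 higher. With the set as a block the median of all genes was 0.01 and that of Wnt genes -0.11.

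Over both ages (6 animals each), lists of fibrous matrix, vessels and growth signals lay lower in experimental animals. Collagen genes were lower in 28 of 29 (median -0.31), ligament fibroblast genes in 17 of 19 (-0.27), endothelial genes in 12 of 12 (-0.32), with Vwf at -0.47 ± 0.20, and smooth muscle genes in 9 of 10 (-0.37). IGF, FGF and PDGF genes were lower in 19 of 22 (-0.30), with Igfbp3, an IGF-binding protein, at -0.55 ± 0.12, and TGF-beta and BMP genes in 23 of 25 (-0.20). The genes with the smallest p were Efemp1, fibulin-3, at -0.66 ± 0.14, Tfpi, an inhibitor of coagulation, at -0.57 ± 0.14, Cdh13 at -0.62 ± 0.15, Ccn3 at -0.90 ± 0.23 and Ly6c at 0.96 ± 0.30. Skeletal muscle genes were higher in 9 of 10 (median 0.49, but 0.27 without E1 and 0.28 without E7, the animals with the 3 highest arrays), oral epithelium genes in 16 of 16 (0.39) and B and plasma cell genes in 7 of 9 (0.16).

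Over all 13624 genes, 0 passed in limma for both ages together (every adjusted p rounds to 1) and 330 had an unadjusted p under 0.05; with the set as a block these were 0 and 1171, and Efemp1, Tfpi and Wnt5a had an adjusted p of 0.0539. Of 16 lists called by camera, 13 lower, adjusted p was 5.25e-09 for collagen, 6.54e-08 for endothelium, 2.69e-06 for TGF-beta and for skeletal muscle, 7.42e-06 for smooth muscle, 7.64e-06 for IGF, 3.25e-05 for ligament fibroblast, 0.000179 for oral epithelium and 0.0351 for B cell genes. With an estimated correlation it was 0.602 for all of these except oral epithelium (0.639) and B cell (0.669), and 0 lists passed. Ligament fibroblast genes did not pass without E1 (median -0.10). Oral epithelium did not pass without C4, nor B cell genes without E3 (0.454). Several differences were not alike in the sets, which here also part the ages: collagen genes had a median of -0.46 in the higher and 0.07 in the lower set, Fmod -2.04 and -0.14, Tagln -1.66 and 0.30, but Efemp1 -0.81 and -0.43, Igfbp3 -0.71 and -0.54, Tfpi -0.74 and -0.47, and Wnt5a -0.59 and -0.55.

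Taken by side, the genes with the smallest p at 31 days in right molars were Tspan2 (-1.63 ± 0.37), Efemp1 (-0.90 ± 0.23), Megf6 (1.22 ± 0.31) and Panx3, a channel protein of osteoblasts and chondrocytes (1.73 ± 0.46, 3 animals each). In left molars of that age (2 against 3 animals) they included Extl1 (1.32 ± 0.33), Adgrl4 (-1.03 ± 0.26), Flt1 (-1.18 ± 0.33) and Col15a1 (-0.83 ± 0.24). At 43 days, right molars had Cd34, a marker of endothelial and blood precursor cells, at -0.86 ± 0.21, Wnt5a at -0.87 ± 0.24, the caveolar coat gene Cav1 at -0.72 ± 0.20 and Ly6c at 1.66 ± 0.49. Left molars had Dpyd at -0.83 ± 0.25, Cdo1 at -0.98 ± 0.30 and the chemokine Ccl2 at 0.58 ± 0.26. In limma 0 genes passed in any of these 4 comparisons, with 260 and 639 genes at an unadjusted p under 0.05 at 31 days (right, left) and 369 and 179 at 43 days. The smallest adjusted p were 0.863 and 0.528 at 31 days and 0.921 for left molars at 43 days, and those of right molars at 43 days round to 1. With the set as a block 0 genes passed in each. An unadjusted p under 0.05 was then found for 350 and 2010 genes at 31 days (right, left) and 584 and 223 at 43 days.

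In experimental animals, Panx3 rose in right against left molars by 1.78 ± 0.25 (adjusted p 0.00974 in limma), and no other gene passed. It was higher on the right in 5 of 5 animals, by 2.06 in E1, 3.23 in E3, 1.98 in E4, 0.45 in E5 and 0.39 in E7. Its mean in right molars was 9.53 ± 0.63 (SD, n = 3) at 31 days and 7.79 ± 0.87 (SD, n = 3) at 43 days, and in left molars 6.95 ± 0.05 (SD, n = 2) and 6.85 ± 0.63 (SD, n = 3). In control animals the means of left and right molars were 7.85 and 7.80 at 31 days and 7.58 and 7.71 at 43 days, and the right was higher in 3 of 6. Osteoblast, osteocyte and cementoblast genes, a list that holds Panx3, were higher on the right in 27 of 29 (median 0.50), among them the mineralization phosphatase Phospho1 (0.88 ± 0.23), Ifitm5 (0.81 ± 0.23) and the parathyroid hormone receptor Pth1r (0.79 ± 0.24). Collagen genes were higher in 26 of 29 (median 0.48), with the prolyl hydroxylase gene P4ha3 at 1.02 ± 0.33 and Crtap at 0.61 ± 0.19, and all 16 oral epithelium genes were lower (median -0.67), with Krt13 at -1.56 ± 0.81. Much of the epithelium value rested on E4, whose right-left difference was -3.68. Without E4 the median was -0.19, with 2 of 16 higher (camera adjusted p 0.0179), and Krt13 was at -0.62. Further genes with small p were Ptx3 (0.93 ± 0.18), Adamts18 (1.06 ± 0.25) and Mdk (1.19 ± 0.29). Ptx3 and Mdk were higher on the right in 5 of 5 animals, but Adamts18 in 3 of 5 (from -0.59 to 2.21). Mdk was also higher on the right in 6 of 6 control animals (mean 0.46).

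**Figure D4:**
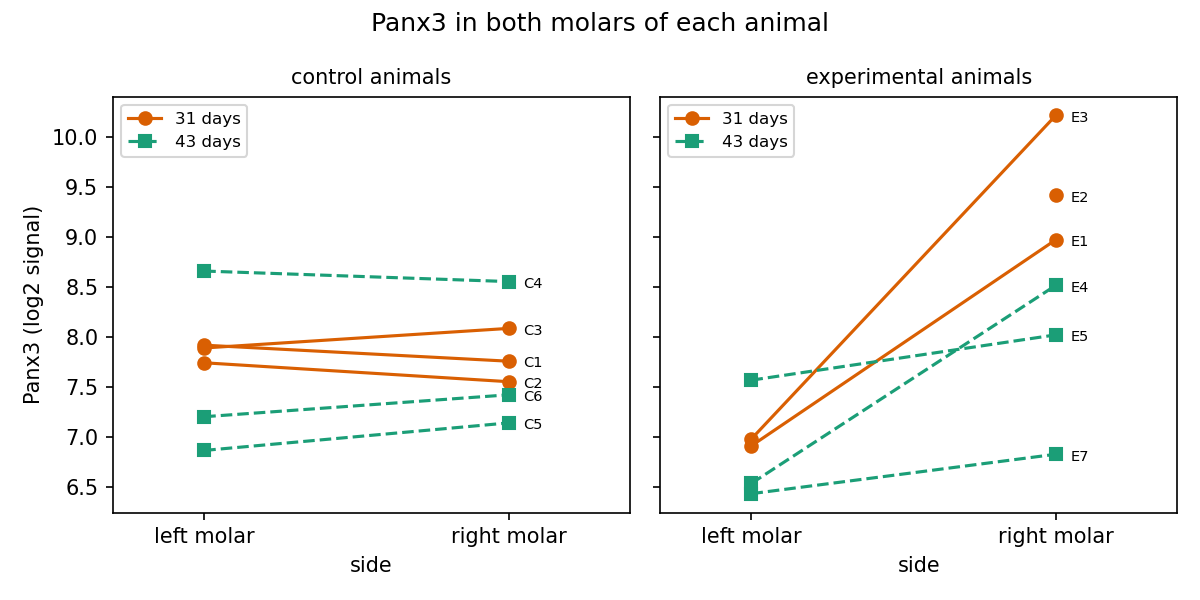
Panx3 log2 value in the left and right molar of each animal, joined by a line, in control and experimental animals (circles, 31 days; squares, 43 days). The right molar is higher in 5 of 5 experimental and 3 of 6 control animals.

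An unadjusted p under 0.05 was found for 2393 genes between the sides of experimental animals. The exact sign-flip p of the 5 Panx3 differences (mean 1.62 ± 1.20 SD) was 0.0625, the smallest that 5 pairs allow, and 0.625 for the 6 control animals. With the set as a block Panx3 differed by 1.77 ± 0.28 (adjusted p 0.0806), within the higher set by 2.61 (0.0768) and within the lower by 0.94 (0.603), and without E3 by 1.55 (0.443). Without E1 16 genes passed, without E7 5, without E4 2 and without E3 0. By camera, adjusted p was 1.94e-05 for osteoblast, 0.000255 for collagen, 0.0476 for TGF-beta (median 0.22) and 1.03e-06 for oral epithelium genes, and 0.974 for each with an estimated correlation. Adjusted over the list alone, 12 osteoblast and 10 collagen genes passed, all higher (7 and 1 with the set as a block), against 1 and 0 over all genes. The osteoblast median was 0.74 in the higher and 0.34 in the lower set, and that of oral epithelium -0.25 and -1.15; over pairs, the right molar had the higher osteoblast mean in 4 of 5 animals (exact p 0.125), the higher epithelium mean in 1 of 5 (exact p 0.1875) and the higher collagen mean in 3 of 5 (from -0.41 to 0.82, exact p 0.25). Collagen had a median of 0.66 in the higher and 0.17 in the lower set, and did not pass without E1 (adjusted p 0.170) or E4 (0.275).

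Control animals also had right-left differences in collagen and osteoblast lists. All 29 collagen genes were higher on the right (median 0.22), as with Lox, which cross-links collagen (0.53 ± 0.24), and so were 24 of 29 osteoblast genes (0.26), with osteocalcin, Bglap, at 0.41 ± 0.19 and Smpd3 at 0.56 ± 0.22, and 17 of 19 ligament fibroblast genes (0.20). All 28 cell cycle genes were lower on the right (median -0.19), with Aurka at -0.30 ± 0.12, and all 14 granulocyte genes (-0.26). The mean of the granulocyte genes, however, was higher on the right in 4 of 6 animals (exact p 0.844) and that of cell cycle genes in 2 of 6 (exact p 0.25). The smallest adjusted p in limma was 0.758, so 0 genes passed, and 555 had an unadjusted p under 0.05. Adjusted p by camera was 1.85e-10 for collagen, 5.63e-08 for osteoblast, 1.48e-05 for ligament fibroblast, 1.96e-07 for cell cycle and 0.0136 for granulocyte genes, and 0.648 for the first 4 and 0.864 for the last with an estimated correlation. The mean of osteoblast genes was higher on the right in 6 of 6 control animals (exact p 0.03125, the smallest possible, among 31 lists tested, so it does not pass an adjustment over them). The sign of the granulocyte list came from C2, whose right-left difference was -2.43. Without C2 its median was 0.21 and camera called it higher (adjusted p 0.00869), while the cell cycle median was -0.08 (0.0457). Ligament fibroblast genes did not pass without C2 (0.0596) or C5 (0.0866). C5 also had the largest right-left difference of collagen (0.78) and osteoblast genes (0.72). Without C5 their means went from 0.24 to 0.12 and from 0.24 to 0.14, and both still passed (0.000735 and 0.000867). The cell cycle median was 0.04 in the higher and -0.47 in the lower set, that of granulocyte genes 0.28 and -1.45, and that of collagen 0.01 and 0.40.

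The right-left difference itself was compared between conditions. Cell cycle genes had a higher right-left difference in experimental animals in 27 of 28 (median 0.31, against 0.13 over all genes), with Mcm2 at 0.45 ± 0.16, Tyms at 0.55 ± 0.21 and Top2a at 0.50 ± 0.20. Oral epithelium genes had a lower one in 13 of 16 (median -0.60), with Krt14 at -0.80 ± 0.42. Panx3 was at 1.74 ± 0.34 (adjusted p 0.172; 0.544 with the set as a block), and at 2.59 and 0.69 within the higher and lower sets. Other genes with small p were the T cell kinase Lck (0.71 ± 0.15), Ptx3 (1.06 ± 0.24) and Irf8 (0.61 ± 0.14). The difference of osteoblast genes had a median of 0.18 and that of collagen genes 0.16, and neither passed (adjusted p 0.454 and 0.954). In limma 0 genes passed (1127 at an unadjusted p under 0.05), and 0 at either age alone (760 at 31 and 438 at 43 days), where Panx3 was at 2.67 ± 0.50 at 31 days and Cav1 at -0.90 ± 0.20 at 43 days. The adjusted p of both the cell cycle and the epithelium list was 4.72e-05 by camera and 0.988 with an estimated correlation. The cell cycle median was 0.26 and 0.37 within the sets, and that of epithelium 0.25 in the higher and -0.20 in the lower set. Values within the sets compare animals of 31 days in the higher and of 43 days in the lower set, so C4 and C2 have no part in them. The epithelium list did not pass without C2 (median -0.20, adjusted p 0.142) or E4 (-0.17, 0.126), nor the cell cycle list without the arrays C2 left and E3 left (0.15, 0.210). Without C2 1 list passed, without C4 4, without C1, C5 or E3 5, without C3 6 and without E7 9. For genes, 1 passed without C4 or E4 over both ages, 1 without C1 and 2 without E2 at 31 days, and 1 without E4 at 43 days.

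Between 31 and 43 days, control animals (3 of each age) had lower values of blood lineage genes at the older age, against a median of all genes of -0.12. All 8 erythroid genes (median -1.09), 14 granulocyte genes (-0.75), 9 B and plasma cell genes (-0.72) and 16 macrophage genes (-0.49) were lower, with Rhag, an erythroid membrane protein, at -1.18 ± 0.35, the neutrophil protease Prtn3 at -0.80 ± 0.28 and Igll1, of B cell precursors, at -0.82 ± 0.37. The platelet genes Pf4 (-1.33 ± 0.34) and Gp9 (-0.81 ± 0.22) and Slfn9 (-1.47 ± 0.31) had among the smallest p. All 16 oral epithelium genes were higher (median 0.57), with Krt14 at 0.48 ± 0.49. In limma 0 genes passed (smallest adjusted p 0.950; 553 at an unadjusted p under 0.05), and 8 lists passed by camera, with adjusted p of 3.67e-05 for erythroid and granulocyte, 0.0007 for macrophage, 0.00705 for B cell and 3.55e-08 for epithelium genes, each 0.68 with an estimated correlation. The macrophage list did not pass without C2 (adjusted p 0.450, median -0.47). Adjusted over the list alone, 1 erythroid gene passed. Erythroid genes were lower in both sets (medians -0.98 and -0.69) and granulocyte genes too (-0.28 and -1.17), while oral epithelium was at -0.20 in the higher and 1.73 in the lower set. The left molar of C2 stood apart, with a granulocyte mean of 9.64 against at most 8.20 in other controls. Its erythroid mean was 10.70, against 8.77 in the right molar of C2, the only other control array labelled 31 days in the lower set. Without C2 left and E3 left, the granulocyte median was -0.44 (adjusted p 0.0556), that of B cell genes -0.41 (0.230) and that of epithelium 0.19 (0.00236). Without C4 4 lists passed, with erythroid (0.119), granulocyte (0.0696) and B cell genes (0.234) not among them, and without C5 14.

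For 43 vs 31 days in experimental animals the ages lay in separate sets of arrays, so age and set could not be told apart among them, and the median of all genes was -0.32. Cell cycle genes were lower at 43 days in 27 of 28 (median -0.47), with Cdk1 at -0.77, Cenpf at -0.64 and Aurka at -0.62, as were the clock gene Ciart (-0.98 ± 0.17), Dpyd (-1.25 ± 0.22) and the DNA repair genes Polq (-0.69 ± 0.14) and Recql4 (-0.64 ± 0.13). Slco2a1, a prostaglandin transporter, was at 0.93 ± 0.27. Of single genes 0 passed in limma (smallest adjusted p 0.0622) and 4151 had an unadjusted p under 0.05; 2026 passed without C2 and 2752 without C4. With the set as a block, which rests on the controls, 722 genes had an unadjusted p under 0.05, the median of all genes was 0.08, Ciart was at -0.53 ± 0.14 and Dpyd at -0.65. Camera called 20 lists, 19 of them higher relative to all genes, although most had negative medians; collagen genes had a median of -0.15 (adjusted p 4.95e-06; 0.495 with an estimated correlation), and 0.55 with the set as a block. The cell cycle list had an adjusted p of 0.0352, and of 0.757 with an estimated correlation, and its median was -0.30 with the set as a block. Without E1 4 lists passed, and neither collagen (0.537) nor cell cycle genes (0.973) did.

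The age effect was also compared between conditions, where the median of all genes was -0.21 as deposited and 0.06 with the set as a block. Granulocyte genes differed by a median of 0.82 (13 of 14 higher), B and plasma cell genes by 0.66 (8 of 9), erythroid genes by 0.62 (8 of 8) and interferon-induced genes by 0.40 (10 of 14). These had adjusted p of 4.2e-14, 2.54e-07, 8.22e-08 and 1.62e-07 by camera, and 0.158 each with an estimated correlation. Without E1 the erythroid median was 0.01 (adjusted p 0.139) and that of granulocyte genes 0.41. Single genes included Dpyd (-1.37 ± 0.31), Ciart (-0.95 ± 0.24), Pf4 (1.19 ± 0.49) and Slamf6 (1.17 ± 0.41). Single genes past the threshold in limma numbered 0 (smallest adjusted p 0.851), and 261 had an unadjusted p under 0.05.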

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

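The tests that use the sets of arrays or the epithelium score, the test of the age labels of C2 and C4, the value of the collagen list without E1, and camera for the difference between the age effects were chosen after the results had been seen.

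The right-left difference of 2 gene lists differed between conditions by camera over both ages, with a median of 0.313 for cell cycle and -0.598 for oral epithelium genes; neither call holds with an estimated correlation (adjusted p = 0.988), and 100 of 100 splits called at least 2 lists (highest other 20). Camera called the age effect of 15 lists different between experimental and control animals, both as deposited and with the set as a block, against a median of all genes of -0.21, and 0 of these calls hold with an estimated correlation (adjusted p from 0.158 to 0.687). Connective tissue and bone lists had medians of 0.140 (ligament fibroblast), 0.0301 (collagen), 0.151 (proteases), -0.0672 (osteoblast), 0.300 (osteoclast) and -0.0672 (osteoclast-regulating signals, where the same gene, Sost, is the median of both lists). Blood lineages had 0.276 (macrophage), 0.817 (granulocyte), 0.616 (erythroid), 0.194 (T and NK cell) and 0.655 (B and plasma cell), and the rest were 0.403 (interferon), -0.0565 (early genes), -0.380 (hypoxia and glycolysis) and 0.00845 (smooth muscle). The negative medians of osteoblast, osteoclast-regulating and early genes were called higher by camera because they lie above the median of all genes. The comparisons of genes left out 8083 probe sets without a listed gene symbol. Among these, 1508 passed in limma between the ages of experimental animals, where age and set cannot be told apart. With the set as a block 0 passed (smallest adjusted p 0.812).

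Panx3 was higher in right than left molars of experimental animals by 1.78 ± 0.25. With the epithelium score as a covariate the difference was 1.51 ± 0.19, and with the mean of the other osteoblast genes 1.15 ± 0.17. Within the lower set, the smaller of the 2 within-set values, it was 0.941 ± 0.404. Each lay over 2 SE above 0, but the SE pool the spread of experimental and control arrays. The SD of the right-left differences was 1.20 in experimental and 0.212 in control animals. The SE thus understate the spread of the experimental pairs. The difference went from 1.78 to 1.51 with the epithelium score, but with such SE this cannot decide whether epithelium is the whole cause. The other osteoblast genes measure the share of bone-forming cells only roughly, so a remainder of 1.15 leaves that share undecided. Both molars of an animal lay in 1 set. A shift between sets therefore cancels in their difference, and the within-set value cannot test it. Epithelium and bone-forming cells may each account for part or all of the difference. Of the 32 ways to turn the sides of the 5 animals, 2 called as many genes (1 in the real arrangement and 1 at most in the others), so chance is not excluded. A difference between the 2 molars of experimental animals remains open as a hypothesis, and cannot be tied to the unopposed tooth because the labels do not say which side that was.

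Collagen genes lay lower in experimental animals at 31 days. Within the higher set their mean difference was -0.485 ± 0.241, just over 2 SE below 0. With only 3 experimental and 2 control animals of this age there, such a margin decides little by itself. The higher set, where most genes lay higher, held all 3 experimental animals of this age, and 1 control lay in the lower set. A shift like that of most genes would thus raise the experimental mean of the list, not lower it. The difference was also larger with the set as a block (-0.59) than as deposited (-0.35). These values argue against the sets as the cause of the lower collagen genes. With the set, epithelium and muscle scores as covariates the mean difference was -0.296 ± 0.146. It was -0.59 ± 0.26 with the set alone and -0.35 ± 0.33 as deposited. Dilution by other tissue may account for part of the difference, and the test leaves this undecided. Without E1 the median of the list went from -0.32 to -0.11, so much of it rests on 1 animal; the 10 splits of the 6 animals are too few for a share under 0.05 (18 lists in the real one, 22 in the highest other). An effect of the condition also remains open.

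Control animal C2, labelled 31 days, lay in the set of arrays of the 43-day experimental animals, and C4, labelled 43 days, in that of the 31-day ones. Exchanged age labels, or arrays processed with the other batch, are candidate explanations. The samples are listed in the series with all of the higher set first and all of the lower set after it. C4 is thus listed with the 31-day experimental animals and C2 with the 43-day ones. This order follows the sets but does not tell the 2 explanations apart. If labels were exchanged, the age differences within the 2 sets would be unrelated across genes, and their correlation was 0.00646, against -0.244 to 0.275 (median 0.0314) for the other 8 ways to single out 1 control per set, 4 of which were higher. This is what an exchange predicts, but a small effect of age would give the same value, genes are not independent replicates, and 9 ways are too few for a share under 0.05. Erythroid genes go the other way, being lower in the animals labelled older in both sets (medians -0.98 and -0.69, 0 of 8 higher in each). In the lower set this rests on the left molar of C2. Its erythroid mean after quantile normalization was 10.70, against 8.77 in the right molar of C2 and 8.65 to 9.43 in C5 and C6. Neither explanation is excluded, and with exchanged labels age and set could not be separated at all.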

How the results depend on the processing

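The set of arrays as a block, fits within sets, the epithelium covariate, leaving out C2 left and E3 left, and the gene-by-gene array weights were chosen after the data had been seen. Array weights by limma's default algorithm did not converge (weights up to 41.7 for E2 right, and 0.135 for C2 right), so their counts are of little use; the gene-by-gene algorithm gave weights of 9.31 and 0.166. Where no cause is given, the cause was not tested.

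Of 242 values of named genes, with 6858 alternative values in all, 6590 of these kept their direction and side of the threshold, 246 passed the threshold newly (95 with array weights and 67 with the gene-by-gene weights), 9 lost it, all of them Panx3 between the sides of experimental animals, and 13 changed sign. Quantile normalization, median centring, the 50th percentile filter, trend and robust variances and 1 value per animal moved none of the values they were run on across the threshold; the 50th percentile filter was run on 167 of the 242 and 1 value per animal on 121. Panx3 was higher on the right under every alternative, by 0.94 to 2.61, with adjusted p from 0.00104 (epithelium score as a covariate) to 0.810, and 0.00467 without E7. It missed the threshold with no replicate block (0.810), animal as a fixed block (0.112), only the groups compared (0.249), set as a block (0.0806), without E3 (0.443), without C2 left and E3 left (0.312; 0.431 with the set as a block), and within the higher (0.0768) and lower (0.603) set.

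Sign changes were few. For experimental against control animals over both ages, the fit within the lower set held the 43-day comparison only. There Col6a3 was at 0.0452, Myl9 at 0.215 and Tagln at 0.299. Between ages of controls within the higher set Dsg3 was at -0.163, Krt14 at -0.189 and Tp63 at -0.179, and with the set as a block without the 2 arrays Dsg3 was at -0.0213 and Krt14 at -0.0354. Aurka between the sides of controls was at 0.0129 within the higher set. Between ages of experimental animals Ifitm3 was at -0.613 with the largest-variance probe set, and Rps26-ps13, a symbol with near-identical copies and so uncertain, at -0.0229 with the set as a block, -0.0218 with the epithelium score added and -0.199 without the 2 arrays.

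For right vs left molar in experimental animals, both ages, the single gene became 2 with no low-value filter and 0 with no replicate block, the animal as a fixed block, only the groups compared, the set as a block, without the 2 arrays, with both of these, and within each set. For right vs left molar in control animals, both ages, 1 gene passed with no filter, 664 with array weights, 52 with gene-by-gene weights and 58 within the lower set. For experimental vs control, 31 days, both molars, 2 passed with the set and the epithelium score and 1 with the set as a block without the 2 arrays; for experimental vs control, 43 days, both molars, 491 with array weights; and for experimental vs control, both ages, both molars, 7 with array weights, 1 with gene-by-gene weights, 4 with set and epithelium score and 1 with the set as a block without the 2 arrays. For experimental vs control, 31 days, right molar, array weights gave 3315 and gene-by-gene weights 67; for experimental vs control, 43 days, right molar, 2556 and 474; for experimental vs control, 43 days, left molar, array weights gave 41; and for experimental vs control, 31 days, left molar, 1 passed with the set as a block without the 2 arrays.

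For right-left difference, experimental minus control, both ages, 2 genes passed with no filter and 7 with array weights; for right-left difference, experimental minus control, 31 days, 66 with no filter, 1 with only the groups compared and 1 with set and epithelium score; and for right-left difference, experimental minus control, 43 days, 2239 with array weights and 507 with gene-by-gene weights. For 43 vs 31 days in control animals array weights gave 9048, gene-by-gene weights 7690 and the lower set 1. By both algorithms the arrays of C2 and C4 had the lowest weights of all (0.166 to 0.227 gene by gene). The weighted comparison thus rests mostly on C5 and C6, of the lower set, against C1 and C3, of the higher set. Age and set can hardly be told apart in these 2 weighted counts. For 43 vs 31 days in experimental animals 3341 passed with no filter, 3004 with no replicate block, 4353 with only the groups compared, 6130 with array weights and 4712 with gene-by-gene weights. The difference between the age effects stayed at 0 genes in limma under every alternative (261 at an unadjusted p under 0.05 in the primary analysis).

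Leaving out 1 animal at a time gave 0 (without E3) to 16 (without E1) genes between sides of experimental animals, 0 to 1 for the right-left difference over both ages and at 43 days, 0 to 2 at 31 days, and 0 to 2752 for 43 vs 31 days in experimental animals (2026 without C2 and 2752 without C4). Lists called were 8 (without E1) to 22 at 31 days, 12 to 18 at 43 days, 13 to 18 over both ages, 1 to 9 for the right-left difference, 4 to 14 for age in controls and 4 (without E1) to 23 in experimental animals. With an estimated correlation and by fry, 0 lists passed in each of the 6 comparisons. No low-value filter left 1 list for the right-left difference, leaving out the 2 arrays gave 4, and the set as a block 13 for age in experimental animals.

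Arrays of experimental and control animals that share a numeral and side deviated from their groups with a median correlation of -0.0267 over 9 pairs (-0.538 to 0.421, 3 above 0.1), so the numerals do not pair them; the numeral as a replicate block left the 7 comparisons of conditions at 0 genes in limma, with from 115 (experimental vs control, 43 days, left molar) to 309 (experimental vs control, 43 days, right molar) at an unadjusted p under 0.05. Without the animal as a block 2 counts moved, as given for Panx3 and for the age of experimental animals. Genes with a mean under 5.81 were not tested, so weakly measured genes are not covered.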

Other observations

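Camera between the sides within a condition and the values of lists with an animal left out were added after the results had been seen; the counts of other splits had been set beforehand.

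Several markers outside the main comparisons varied between the molars of an animal. In control animals the right molar had a lower mean of skeletal muscle genes in 6 of 6 animals (exact p 0.03125, the smallest possible, among 31 lists tested), and its list of junctional epithelium and enamel organ genes was higher by a median of 0.33 (camera adjusted p 0.00714; 0.648 with an estimated correlation), as were dental pulp and odontoblast genes (0.45; 0.00908 and 0.648). Neither list passed without C5 (adjusted p 0.243 and 0.115). In experimental animals the right molar had the higher junctional epithelium mean in 5 of 5 (mean 0.41, exact p 0.0625, the smallest possible). The same held for dental pulp (mean 0.50), adipocyte (0.17) and mast cell genes (0.24), again among 31 lists tested. Podoplanin, Pdpn, a gene of osteocytes and lymphatic vessels, was at 0.44 ± 0.12 and the keratin Krt76 at -2.25 ± 0.83 between the sides of controls, and neither passed (adjusted p 0.963 for both). Pdpn was higher on the right in 6 of 6 control animals, and Krt76 in 3 of 6 (from -5.91 to 0.70).

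The arrays of the 2 sets also differed in how often 2 arrays held exactly the same value for a probe set. Pairs within the higher set shared 181 to 699 values (median 544, 55 pairs), pairs within the lower set 3 to 23 (median 11, 66 pairs) and pairs between the sets 0 to 2 (108 of 132 pairs at 0). A further test, of an admixture of gingiva as the source of the lower oral epithelium genes in right molars of experimental animals, gave a mean correlation of 0.884 among these genes. Markers of 1 tissue vary together whatever parts the sides, so this value decides nothing. The test was taken out of the patterns weighed after its result had been seen, to make room for the test of C2 and C4.

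Other splits of the same animals were fitted, with both molars of an animal kept together. Where the real count is 0 every split reaches it, so for those counts the share says nothing about chance, and only the highest other count is of use. Comparisons with 10 splits have too few for a share under 0.05. For genes, the real split and the highest other called 0 and 0 (31 days), 0 and 2 (43 days), 0 and 0 (right, 31 days), 0 and 9 (right, 43 days), 0 and 0 (left, 43 days), 0 and 0 (right-left difference, 31 days), 0 and 1 (right-left difference, 43 days) and 0 and 0 (age in experimental animals), where 10 of 10 is the only possible share. For age in control animals the real count was also 0, and 1 other split called 6826 genes, which points to a structure of the samples. It sets C1, C3 and C4 against C2, C5 and C6, which is the split of the 2 sets of arrays. With the set as a block the real comparison of ages called 0 genes, as it did without the block, so that 0 does not test this structure. For lists, 2 of 10 splits called as many as the real 18 at 31 days (highest other 22), 3 of 10 as the real 15 at 43 days (17), 8 of 10 as the real 8 for age in controls (16) and 4 of 10 as the real 20 for age in experimental animals (22).

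Where more splits were possible, chance was not excluded for the counts that could be tested. For both ages, 29 of 100 drawn splits called at least the real 16 lists (highest other 21), for the right-left difference between conditions 100 of 100 at least the real 2 lists (highest other 20), and between the sides of experimental animals 2 of 32 splits at least 1 gene (highest other 1). Counts of genes that were 0, and so reached by 100 of 100 or 32 of 32 splits whatever the data, had a highest other of 0 for both ages, 6 for the right-left difference, 0 for the difference between age effects and 2 between the sides of control animals.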
